A study of Mus musculus with 3 samples.

How the data were processed

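Chromatin-fraction RNA of Lipid A-stimulated mouse bone marrow-derived macrophages was measured in 3 libraries of 1 group, labelled biological replicates 1 to 3. The group, the replicate number, the stimulus (100 ng/ml for 25 min) and the RNA amount (1000, 250 and 500 ng in replicates 1, 2 and 3) were taken from the labels.

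For each library the authors deposited a gene table and a transcript table with expected counts and TPM, whose column names are those RSEM writes, per the file headers. A second deposited transcript table holds estimated counts and TPM under the column names of kallisto, per the file headers. Deposited TPM were scaled by the authors over all entries of a table, small RNAs and spike-ins included. The tables refer to assembly mm10 and annotation release M21, per the deposited readme files, which were used for nothing else. The aligner, tool versions, strand setting and read filters are not given in the sources used here. All 55536 genes with an ENSMUSG identifier were found in the GENCODE M21 annotation of the same assembly. It gave gene names, coordinates, gene types and transcript types. The tables also held 26248 tRNA and 97 spike-in entries.

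Levels were computed from the deposited expected counts. Each count was divided by the gene's effective length and scaled to TPM over genes with a mean length of at least 300 nt. The entries left out were shorter genes, tRNA and spike-in entries. Together they held 67.1%, 62.1% and 61.7% of the deposited TPM in replicates 1, 2 and 3. A gene's level in a contrast was the mean over libraries of log2(TPM + 1), so folds between lists are on that scale and understate differences of low genes. The pseudocount was 1. Values per gene are mean ± SD over 3 libraries.

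The gene lists (19 lists, 489 entries, without shared members), the list contrasts, the test of RNA amount and the biological coefficient of variation were fixed before the data were examined. The ratios between libraries, their matched random lists and the tests of the closing section were chosen after seeing the data. Rmrp, mt-Nd4l and mt-Atp8 fell under the length limit and were left out of their lists, as was Norad, a name that no gene of the annotation carries. Lists were compared by the difference in mean level with a two-sided permutation test of list membership over genes (100000 resamples). The retained-intron share was the percent of a gene's RSEM transcript counts on transcripts annotated as retained introns, for genes with at least 50 expected counts. The 6 level contrasts and 3 retained-intron contrasts formed 1 family of 9 for Benjamini-Hochberg adjustment, and an adjusted p under 0.05 was called. Simulated pairs of lists, 200 per shift with 63 genes a pair, were drawn from the levels of all genes of at least 300 nt. With fewer resamples, an unadjusted p under 0.05 was reached in 6% with no shift, 47.5% at 1 log2 unit, 97% at 2 and 100% at 3. These rates do not describe the adjusted test on the fixed lists.

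The change with RNA amount was fitted with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood F test) in R 4.3.3 on expected counts rounded to whole numbers, as log2 change per doubling. The TMM factors were 1.11, 0.931 and 0.964. The standard error was derived from the F statistic. On simulated counts, of which 13520 to 13721 genes passed the filter, with 200 genes changed by 0.5 log2 units per doubling, the test recovered 78 at a dispersion of 0.02 with 8 false calls, and 0 at a dispersion of 0.1. At 1 log2 unit it recovered 198 and 26, with 11 and 1 false calls. The biological coefficient of variation came from edgeR's common dispersion without covariates. Ratios of replicate 1 to the other libraries were log2 CPM (counts scaled to library size) with TMM factors and pseudocount 1, centred on the median gene, and were described by their percentile among 10000 random lists matched on expression. Sequences of mitochondrial genes were compared with the annotated nuclear transcripts with BLAST 2.17.0 (at least 95% identity over at least 80% of the length). Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

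Alternatives fixed beforehand were the deposited TPM, the kallisto-type table, a pseudocount of 0.1, a minimum mean of 0.1 TPM, medians, CPM without gene length, other count minimums (10 and 200) and shares of TPM for retained introns, RLE size factors, DESeq2 1.42.0, no count filter, genes of any length, other orders of the RNA amounts, and leaving out each replicate. Leaving out the ribosomal DNA locus genes, and repeating list counts, named genes and list calls under other settings, were added after seeing the data.

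Named genes followed a rule fixed beforehand: 22 response, macrophage and nuclear RNA genes always, the 4 highest and 2 lowest of each list, the 10 highest genes of all, the 5 highest and 3 lowest retained-intron shares of rapid response genes, and the 5 largest increases and decreases with RNA amount. For brevity some of these are given only as part of their list's counts. The phiX174 and tRNA entries were left out of levels and tests. Genes that overlap others or have near-identical copies are uncertain, since the strand setting is not given in the sources used here and expected counts split shared reads.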

Results

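The series measured RNA bound to chromatin in mouse bone marrow-derived macrophages, primary phagocytes grown from marrow of the C57BL/6J strain. The cells had been stimulated for 25 min with 100 ng/ml Lipid A, the part of bacterial lipopolysaccharide that activates the receptor TLR4. Total RNA of the chromatin fraction, which is rich in transcripts still being made, was sequenced after depletion of ribosomal RNA. All 3 libraries, labelled biological replicates 1 to 3, belong to this 1 group, and no control is analysed here. The levels therefore compare genes within stimulated cells and do not show that a gene was induced. The labels give the RNA used for the libraries as 1000 ng in replicate 1, 250 ng in replicate 2 and 500 ng in replicate 3. They do not say whether the replicates came from separate animals, so p-values that rest on the replicates measure the spread between these samples.

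The gene tables held 13525994 expected counts in replicate 1, 19230763 in replicate 2 and 19207049 in replicate 3. At least 10 counts fell on 14627, 15080 and 14990 genes. A gene with 0 counts could still hold up to 0.222, 0.156 and 0.156 CPM (counts scaled to library size) in replicates 1, 2 and 3, counting error only. Over 14928 genes the chi-square per gene was 191 between replicates 1 and 2, 132 between replicates 1 and 3, and 21.5 between replicates 2 and 3. This compares with counting error only, which separate samples exceed at such depth, and the value was lowest for replicates 2 and 3. It is a mean in which genes with very high counts weigh most, such as Gm26917 (1001924, 4322405 and 3729892 counts in replicates 1, 2 and 3). The median absolute log2 ratio, centred on the median gene, was 0.374, 0.3245 and 0.174 for the pairs in the same order.

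Signal of a ribosomal locus and noncoding RNAs headed the chromatin fraction. By mean level the most abundant gene of at least 300 nt was Gm26917 (mm10, chromosome 17, 39843013 to 39846341), at 115478 ± 52517 TPM (transcript abundance scaled for gene length and library size; SD, n = 3), although Malat1 was above it in replicate 1 (61145 against 55324 TPM). It lies beside Gm42418 (39846958 to 39848788) on the same strand and CT010467.1 (39846353 to 39848827), annotated as ribosomal RNA and next in level at 54119 ± 37555 TPM, on the opposite strand. These 3 genes were taken as the ribosomal DNA locus from that annotation alone, without examining reads, and together took 8.46%, 27.1% and 23.1% of the counts of replicates 1, 2 and 3. Malat1, a nuclear speckle RNA, reached 44534 ± 15438 TPM, and Neat1, the scaffold of paraspeckles, 6394 ± 765 TPM (SD, n = 3). The transcription regulator Rn7sk followed Malat1 among the fixed noncoding list at 19038 ± 2264 TPM. The small RNA genes Scarna10 and Gm22009, which lie inside Ncapd2 and Kpna4, reached 25860 ± 4530 and 15687 ± 6866 TPM. Rn7s1 and Rn7s2, near-identical 7SL RNA genes, carried the same value of 31292 ± 7040 TPM in the tables, so their reads cannot be assigned to either. Of 28 noncoding genes measured, 24 reached 1 TPM, while Meg3 had 1 count in all and Mirt2 none.

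The immediate early genes, transcription factors and signal regulators known to be switched on within minutes, stood far above the inflammatory genes known to need longer stimulation. Of 33 immediate early genes, 30 had a mean of at least 1 TPM, and the list's median was 152 TPM against 0.521 TPM for the late inflammatory list. The MAP kinase phosphatase Dusp1 was the highest at 737 ± 112 TPM (SD, n = 3), followed by the nuclear receptor Nr4a1 at 675 ± 120, the G protein regulator Rgs1 at 653 ± 270 and the AP-1 subunit Fos at 560 ± 198 TPM. The transcription factor Egr1 reached 286 ± 126 TPM and Ier2 254 ± 72.5 TPM. Arc, with a mean of 0.312 TPM, and Fosl1 were lowest. The mean level of the list was 4.79 log2 units above that of the late list (27.7-fold; 33 and 30 genes; two-sided permutation test over genes, adjusted p = 2.25e-05). The difference was 4.62, 4.86 and 4.90 in replicates 1, 2 and 3. An unadjusted p of 1e-05 is the smallest that 100000 resamples can give, and genes are not independent replicates.

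Primary targets of NF-kB, the transcription factor that TLR4 activates, were abundant too. Of 50 measured, 48 had at least 1 TPM and 36 at least 100 TPM, with a median of 144 TPM. Tnfaip2 (chromosome 12, 111442469 to 111455018) led at 3257 ± 1563 TPM (SD, n = 3), followed by the transcription factor Irf1 at 1823 ± 908, the mitochondrial superoxide dismutase Sod2 at 1420 ± 977 and Tnfaip3, which encodes the NF-kB inhibitor A20, at 1104 ± 598 TPM. The cytokine genes Il1b and Tnf (chromosome 17, 35199381 to 35202007) reached 1095 ± 699 and 568 ± 266 TPM. The chemokine genes Cxcl2 and Cxcl1 reached 994 ± 371 and 251 ± 120 TPM. Nfkbia, the gene of the NF-kB inhibitor IkBα, stood at 961 ± 231 TPM. Lif and Cxcl3 were lowest, at 0.580 ± 0.543 and 0.514 ± 0.222 TPM. Without replicate 1 the means of Sod2, Il1b and Lif were 862, 695 and 0.266 TPM. The list lay 5.72 log2 units above the late list (52.7-fold; 50 and 30 genes; permutation test over genes, adjusted p = 2.25e-05), with 6.03, 5.47 and 5.65 in replicates 1, 2 and 3.

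Immediate early and NF-kB primary genes did not differ in mean level by a called amount. The immediate early mean was lower by a log2 difference of -0.93 (33 and 50 genes; permutation test over genes, adjusted p = 0.142), with -1.41, -0.61 and -0.75 in replicates 1, 2 and 3. The order of the lists depended on the measure. The difference of medians was 0.19 (adjusted p = 0.823), whereas levels from the kallisto-type transcript table gave -1.31 (adjusted p = 0.0291). The adjusted p ran from 0.0291 to 0.823 over 10 alternatives.

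Genes of the interferon response held intermediate levels. Of 30 measured, 26 had at least 1 TPM, with a median of 35.6 TPM (61.4, 17.5 and 27.2 TPM in replicates 1, 2 and 3) that was 21.9 TPM without replicate 1. Oasl2, an antiviral oligoadenylate synthetase-like gene, was highest at 244 ± 68.8 TPM (SD, n = 3), beside Oas2 at 228 ± 51.2, Mx1 at 205 ± 88.4 and the GTPase gene Gbp5 at 229 ± 272 TPM. Gbp5 (chromosome 3, 142493978 to 142522344) had the largest SD of the list, at 540, 35.1 and 112 TPM in replicates 1, 2 and 3. Cxcl10, a chemokine induced by IRF3 and interferon, had 99.2, 22.6 and 33.6 TPM. Without replicate 1 the mean of Gbp5 was 73.5 TPM. Ifit1 reached 8.41 ± 5.53 TPM (5.33 without replicate 1), and the chemokine gene Ccl5 had 29, 5 and 23 counts. Ifnb1, the interferon beta gene itself (chromosome 4, 88522025 to 88522774), had 0 counts in every library, and Cxcl11 had 1, 1 and 0.

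The interferon response list lay 3.10 log2 units above the late inflammatory list (8.58-fold; 30 genes in each; permutation test over genes, adjusted p = 2.25e-05), with 3.36, 2.83 and 3.11 in replicates 1, 2 and 3. The NF-kB primary list lay 2.62 log2 units above the interferon response list (6.14-fold; 50 and 30 genes; permutation test over genes, adjusted p = 3.6e-05). Here the replicates gave 2.67, 2.64 and 2.54. Cxcl10 and Cxcl11 lie inside Art3 on the opposite strand, and whether the counting used strand is not given in the sources used here.

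Late inflammatory genes mostly had low levels, though some of those below 1 TPM were still counted in every library. Of 30 measured, 18 had a mean below 1 TPM and 4, among them Il19 and Il33, had no counts. The cytokine gene Il6 had 18, 5 and 21 counts in replicates 1, 2 and 3, a mean of 1.10 ± 0.820 TPM (SD, n = 3; 0.702 without replicate 1). Il12b, a subunit of interleukin 12, had 56, 1 and 15 counts, and Nos2, the inducible nitric oxide synthase, 7, 3 and 0. Of the 12 genes at 1 TPM or more, the highest were Il10, an anti-inflammatory cytokine gene, at 95.6 ± 57.4 TPM, Il18bp at 64.6 ± 18.9, Il1rn at 41.2 ± 18.4 and Acod1, the itaconate-producing enzyme, at 33.9 ± 40.4 TPM. Il18bp overlaps Numa1 on the opposite strand, so its count is uncertain. Acod1 had 80.5 TPM in replicate 1 against 8.49 and 12.8 TPM in replicates 2 and 3, a mean of 10.6 TPM without replicate 1.

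**Figure D1:**
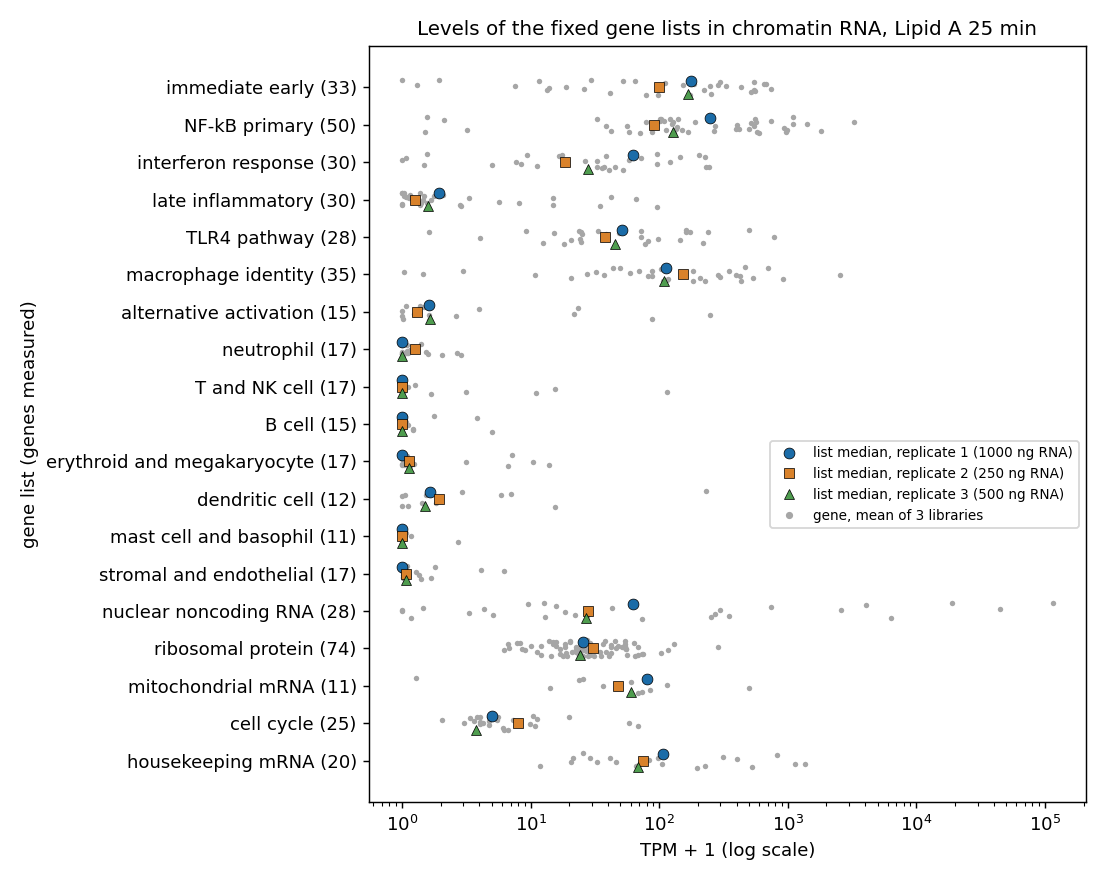
Levels of 19 gene lists, each on its own line, on a logarithmic axis of TPM + 1; grey points are genes (mean of 3 libraries) and coloured symbols are the list medians of replicates 1, 2 and 3. The immediate early and NF-kB primary medians lie at 90.9 TPM or more in every library, the late inflammatory medians between 0.259 and 0.941 TPM.

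The TLR4 pathway and macrophage identity genes were abundant, whereas markers of other cell types were nearly silent. Of 28 pathway genes, 27 had at least 1 TPM: the kinase gene Ikbke was highest at 775 ± 190 TPM (SD, n = 3), followed by the co-receptor gene Cd14 at 496 ± 121, the kinase gene Tbk1 at 240 ± 52.2 and the transcription factor gene Irf3 at 217 ± 38.5 TPM. Tlr4 itself stood at 23.6 ± 2.21 TPM, and the adaptor gene Tirap and the serum protein gene Lbp were lowest at 3.06 ± 0.906 and 0.615 ± 0.379 TPM. Of 35 identity genes, 33 had at least 1 TPM, with Gpnmb at 2536 ± 426, the cathepsin gene Ctsb at 920 ± 147, the leukocyte gene Ptprc at 704 ± 350, the M-CSF receptor gene Csf1r at 535 ± 152 and the lysozyme gene Lyz2 at 422 ± 171 TPM. Lyz1, a close copy of Lyz2, had 0.455 ± 0.032 TPM, and Cx3cr1 was lowest.

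Among 106 markers of neutrophils, T, NK and B cells, erythroid cells and megakaryocytes, dendritic cells, mast cells and basophils, and stromal and endothelial cells, 22 reached 1 TPM and 33 had no counts. The identity list lay 5.88 log2 units above them (58.8-fold; 35 and 106 genes; permutation test over genes, adjusted p = 2.25e-05), with 5.99, 5.84 and 5.79 in replicates 1, 2 and 3. The markers above 10 TPM were Tcf4 at 232 ± 56.3, Cd28 at 114 ± 65.5, Cd4 at 14.6 ± 4.29, Bst2 at 14.6 ± 2.96, Alas2 at 12.9 ± 4.52 and Cd5 at 10.1 ± 3.79 TPM (SD, n = 3). Alas2 overlaps Apex2 on the opposite strand, so its count is uncertain. The T cell gene Thy1, the B cell gene Pax5 and the erythroid gene Hbb-bt had no counts. The highest neutrophil marker, Ngp, had 1.87 ± 0.881 TPM, the highest mast cell marker, Kit, 1.71 ± 0.751 and the highest endothelial marker, Kdr, 5.23 ± 1.83 TPM. Of 15 genes of alternative activation, 6 reached 1 TPM, with Tgm2 at 246 ± 67.2 and Il4ra at 86.3 ± 10.3 TPM, and Retnla and Chil4 had no counts.

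All 74 ribosomal protein genes reached 1 TPM, with a median of 25.1 TPM, Rpl10 being highest at 284 ± 39.7 TPM and Rpl29 lowest at 5.24 ± 2.18 TPM (SD, n = 3). The 20 housekeeping genes had a median of 89.6 TPM, led by the ferritin gene Fth1 at 1354 ± 289 and the elongation factor gene Eef1a1 at 1131 ± 427 TPM, with Pgk1 lowest at 10.9 ± 1.94 TPM. Of 11 mitochondrial mRNAs of at least 300 nt, 10 reached 1 TPM, with mt-Co1 at 502 ± 237 TPM and mt-Cytb at 72.2 ± 23.5 TPM. Of these 10, mt-Nd3, mt-Co2 and mt-Atp6 had 0 counts in 2 of the 3 libraries each. These genes and mt-Co3, the gene below 1 TPM, have near-identical nuclear copies, so this count is uncertain. The 25 cell cycle genes had a median of 4.50 TPM, with the proliferation marker Mki67 at 68.0 ± 56.7 (35.3 without replicate 1) and Pcna at 57.0 ± 19.0 TPM.

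**Figure D2:**
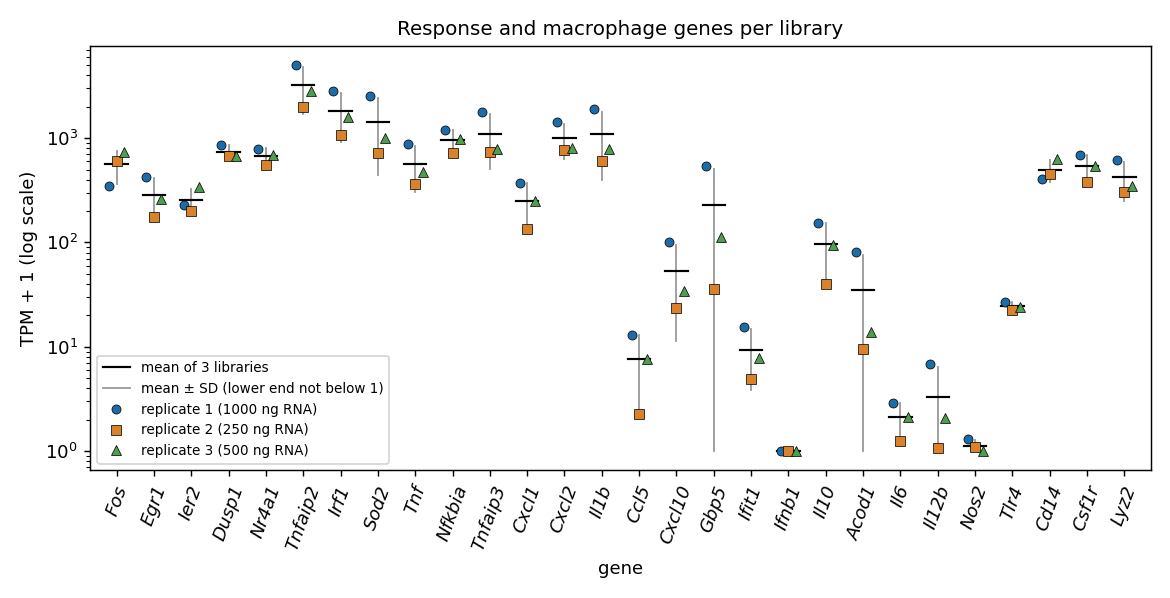
TPM + 1 of response and macrophage genes on a logarithmic axis; symbols are replicates 1, 2 and 3, black bars their means and grey lines mean ± SD (n = 3). Tnfaip2 is the highest at a mean of 3257 TPM, Ifnb1 is at 0 in each library, and Gbp5 spans 35.1 to 540 TPM.

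Transcripts annotated as retained introns took part of the counts of many genes. Over 5918 genes with at least 50 expected counts and an annotated retained-intron transcript, such transcripts took a mean of 32.0% of a gene's counts (median 25.9%), each gene weighted alike; whether these counts are incompletely spliced RNA was not tested. Among the 37 immediate early and NF-kB primary genes tested, Dusp1 had the highest share at 96.3% ± 2.14 (SD, n = 3), followed by Tnip3 at 95.7% ± 1.99, the lectin gene Clec4e at 94.8% ± 1.70, Cxcl1 at 91.3% ± 2.33 and Rgs1 at 88.8% ± 1.46. Nfkbia at 3.48% ± 0.614, Tnip1 at 6.63% ± 3.03 and the kinase gene Pim1 at 7.43% ± 5.14 were lowest. The mean share of these rapid response genes was 46.8%.

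None of the 3 lists tested differed from the rapid response genes by a called amount. The share was 18.3 percentage points above that of 14 macrophage identity genes, which averaged 28.5% (permutation test over genes, adjusted p = 0.0964). Against 47 ribosomal protein genes at 54.0% the difference was -7.19 points (permutation test over genes, adjusted p = 0.307). It ran from -18.1 points as a difference in median to -0.996 points as a share of TPM over 8 alternatives. Against 16 housekeeping genes at 45.5% the difference was 1.31 points (permutation test over genes, adjusted p = 0.890), and its sign turned under other settings. The shares depend on which retained-intron transcripts the annotation holds, and estimated counts split reads between overlapping transcripts.

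The labelled RNA amount was the only recorded difference between the libraries, so each gene was tested for a change with it. The edgeR quasi-likelihood test called 1032 of 13993 genes, 633 higher and 399 lower with more RNA, at a Benjamini-Hochberg adjusted p under 0.05. The largest increases per doubling of RNA were 2.07 log2 units (SE 0.21) for Mir155hg, the host gene of miR-155, 1.81 (SE 0.21) for the pseudogene Gm47727, 1.77 (SE 0.13) for Gbp5, 1.72 (SE 0.28) for Art3 and 1.70 (SE 0.26) for Gm9973. Gm47727 lies within Aoah on the same strand, and Art3 overlaps Cxcl10, so their counts are uncertain. The largest decreases were -1.67 (SE 0.29) for Akap2, which overlaps Pakap, -1.56 (SE 0.25) for CT010467.1, -1.53 (SE 0.28) for the intermediate filament gene Nes, -1.47 (SE 0.31) for the helicase gene Pif1 and -1.35 (SE 0.32) for Gm20721, which overlaps Gnas. Pif1, at 0.509, 2.86 and 0.473 TPM in replicates 1, 2 and 3, did not follow the order of the amounts. The TPM of the other genes named here did. Each amount was 1 library and the fit had 1 residual degree of freedom. The amount therefore cannot be told apart from any other difference between the replicates. DESeq2 called 386 genes (280 higher and 106 lower) and kallisto-type counts 369 with edgeR.

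By list, NF-kB primary genes were higher with more RNA in 30 of 47 tested genes and lower in 0; adjusted over the list alone, 34 and 0 passed. Among them Sod2 rose by 0.75 log2 units per doubling (SE 0.13), Il1b by 0.71 (SE 0.13), Irf1 by 0.64 (SE 0.13) and Tnf by 0.45 (SE 0.13), all by edgeR, while Nfkbia, at 0.19 (SE 0.13), and Tnfaip2, at 0.21 (SE 0.14), did not pass. Interferon response genes were called higher in 13 of 26 and lower in 0 (16 and 0 adjusted over the list alone), Cxcl10 by 1.23 (SE 0.15). Late inflammatory genes were higher in 5 of 10 (6 adjusted over the list alone), Acod1 by 1.46 (SE 0.17) and Il10 by 0.81 (SE 0.15). Immediate early genes went both ways, 9 higher and 3 lower of 31 (12 and 5 adjusted over the list alone). Egr1 rose by 0.43 (SE 0.13), whereas Fosb fell by 0.77 (SE 0.20), Srf by 1.03 and Plk3 by 0.79, the last 3 named after their values were seen. Fos itself, at -0.48 (SE 0.16), did not pass. Of 74 ribosomal protein genes 6 were lower and 0 higher (6 and 0 adjusted over the list alone), Rpl3 falling by 0.75 (SE 0.14) and Rpl10a by 0.63 (SE 0.14). Of 24 cell cycle genes 4 were lower and 1 higher (16 and 1 adjusted over the list alone). The lower ones numbered 2 with RLE size factors, 8 without the count filter, 1 with kallisto-type counts and 0 with DESeq2. The list's median log2 ratios to the other libraries were -0.43, 0.87 and -0.45 in replicates 1, 2 and 3. Replicate 2 stood apart, and replicates 1 and 3 did not follow the order of the amounts. No housekeeping gene of 20 was called (0 adjusted over the list alone). With kallisto-type counts the calls fell to 15 NF-kB primary, 8 interferon response, 3 late inflammatory and 2 higher immediate early genes; DESeq2 called 25, 10, 2 and 5.

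**Figure D3:**
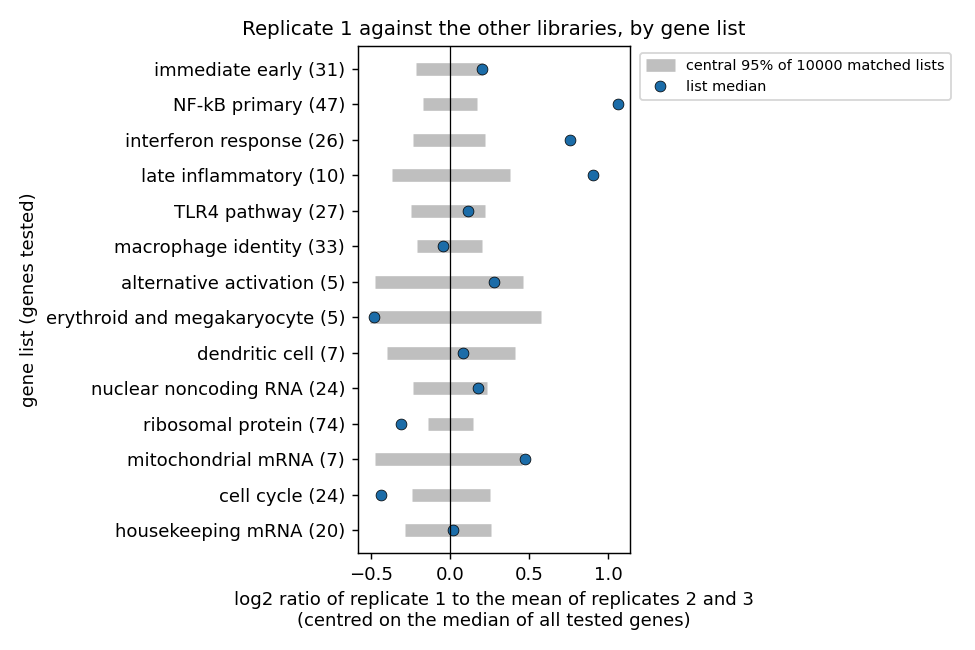
Median log2 ratio of replicate 1 to the mean of replicates 2 and 3 per gene list (points, centred on the median of all tested genes; a comparison chosen after seeing the data), with the central 95% of 10000 random lists matched on mean expression (grey bars). NF-kB primary genes lie at 1.06, interferon response genes at 0.76 and late inflammatory genes at 0.90, above their bars, as do mitochondrial mRNAs at 0.48 by a small margin; ribosomal protein genes at -0.31 and cell cycle genes at -0.43 lie below theirs.

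The spread between replicates over all genes, edgeR's biological coefficient of variation, was 0.247 over 13993 genes. Without replicate 1 it was 0.140, without replicate 2 0.259 and without replicate 3 0.301. The median NF-kB primary gene was 2.08-fold higher in replicate 1 than in the other libraries, and the median ribosomal protein gene 0.809-fold. Replicate 1 also carried the lowest share of ribosomal DNA locus counts, 8.46%.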

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

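These values lay outside the measurements compared above, and no test of them was chosen after they were seen. With no control library, the counts were listed because they exceed the 3 that a count of 0 allows. DNA of the phage phiX174, which is added to sequencing runs or libraries as a control, took 207165 expected counts in replicate 1, 68680 in replicate 2 and 59094 in replicate 3. Entries for tRNA genes held 42, 30 and 32 expected counts in replicates 1, 2 and 3. These are sums over 26248 entries, so exceeding a limit meant for a single entry does not set them apart. The entries left out of the recomputed levels were genes under 300 nt, tRNA and spike-in entries. Together they carried 67.1%, 62.1% and 61.7% of the deposited TPM in replicates 1, 2 and 3.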

How the results depend on the processing

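Leaving out the ribosomal DNA locus genes, and the repeats of list counts, named genes and list calls, were chosen after seeing the data. The numbers of list members at 1 TPM or more changed little in 89 repeats and moved further in 6. For list genes called higher with more RNA, the numbers changed little in 42 repeats and moved further in 14. For those called lower the figures were also 42 and 14. The 5 called level contrasts kept their direction and stayed called under all 10 alternatives each: immediate early against late inflammatory genes ran from 4.02 to 6.65 log2 units, NF-kB primary against late from 4.88 to 7.16, interferon response against late from 2.44 to 4.44, NF-kB primary against interferon response from 2.01 to 2.91, and macrophage identity against other cell types was lowest at 4.82. Leave-one-out over the 3 replicates gave 4.74 to 4.88, 5.56 to 5.84, 2.97 to 3.23, 2.59 to 2.66 and 5.82 to 5.92 for these 5, in the same order, and -1.08 to -0.68 for immediate early against NF-kB primary genes. Immediate early against NF-kB primary genes became called with kallisto TPM (-1.31, adjusted p = 0.0291) and changed sign as a difference in median (0.19, adjusted p = 0.823); the cause was not tested. No retained-intron contrast was called under any of 8 alternatives, and leave-one-out gave -7.50 to -6.58 points against ribosomal protein, 17.8 to 19.2 against macrophage identity and 0.909 to 1.86 against housekeeping genes; the one against housekeeping genes changed sign with at least 200 expected counts (-0.42 points) and as a share of TPM (-1.26 points), the cause not tested, and the adjusted p of the one against macrophage identity genes ran from 0.0547 to 0.315. The 1032 genes changing with RNA amount became 994 with RLE size factors, 1156 without the count filter and 1101 with genes of any length. They became 369 with kallisto counts, 289 of them shared with the 1032, and 386 with DESeq2, all shared. DESeq2, with its default filtering by mean count left on, gave an adjusted p for 8024 genes only. The cause of the smaller numbers called was not tested. With the amounts reassigned so that replicate 1 took the middle of the input order edgeR called 0 genes (78 at an unadjusted p under 0.05), and with replicate 2 in the middle of the input order 0 (976). The biological coefficient of variation ran from 0.140 to 0.301 on leaving out 1 replicate, lowest without replicate 1 (the cause was not tested), and from 0.230 to 0.262 under 4 other settings. No replicate could be left out of the RNA amount fit, which would keep no residual degree of freedom. No paired analysis was possible because the libraries form 1 group. Of the mean TPM of named genes under other settings, 605 stayed within 1 SD between replicates and 87 did not. Leaving out 1 of 3 replicates cannot move a mean by 1 SD, so those settings all fell among the 605. The 87 came from kallisto TPM or from leaving out the ribosomal DNA locus genes. Depth limits what a count of 0 shows, to 0.222, 0.156 and 0.156 CPM in replicates 1, 2 and 3.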

Other observations

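The tests of the stage of the response, of gene span, of the RNA amount, of the common factor and of depth, and the list ratios between libraries, were chosen after the replicate 1 pattern was seen, and levels of single response genes had been seen before the other tests of it were written. Most cell cycle genes were highest in replicate 2. Over 24 genes the median log2 ratio of replicate 2 to the other libraries was 0.87 in CPM, above all 10000 random lists matched on expression, and 0.80 in TPM. The helicase subunit gene Mcm6 had 7.74, 15.7 and 7.24 TPM in replicates 1, 2 and 3. By TPM 20 of 25 genes were highest in replicate 2 and 5, Mki67, Pcna, Bub1, Cdk1 and Ccnb2, in replicate 1, the last 3 named after their values were seen. Mki67 had 133 TPM in replicate 1 against 36.6 and 34.0 TPM. The collagen genes Col1a1 and Col3a1 had 0 counts in replicate 1, 25 and 14 in replicate 2, and 30 and 20 in replicate 3.

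The paralogous immune receptor genes Lilrb4a and Lilr4b, named after their values were seen, stood among the 20 most abundant genes at 3290 ± 1195 and 2802 ± 992 TPM (SD, n = 3). Retained-intron transcripts took a mean of 99.9% and 95.5% of their counts, though reads shared between close paralogs leave both values uncertain.

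Of the 78 immediate early and NF-kB primary genes tested, 62 were higher in replicate 1 (median log2 ratio to the other libraries 0.65), carried by the NF-kB primary genes (1.06, 43 of 47 higher), while the immediate early genes (0.20, 19 of 31 higher) lay inside their matched lists' range, up to 0.21, but below all matched lists in replicate 2 (-0.33). A larger share of ribosomal DNA locus reads in replicates 2 and 3, assigned by annotation only, scales all other genes alike. Centring on the median gene removes such a factor. The 78 genes lay 0.63 above the housekeeping genes (permutation test over genes, p = 0.021), but this restates the pattern and could not have decided otherwise. Lower depth of replicate 1 was taken to act alike on genes of the same level. The median of 0.65 lay above 0.13, the upper end of the central 95% of lists matched on expression. That comparison had already described the pattern, so it is no separate test of depth. Both show only that these genes stood apart from housekeeping genes and from genes of the same level. Less mature RNA in replicate 1 may contribute. Ribosomal protein genes lay at -0.31, below all matched lists, but at 0.43 in replicate 2, above all, and at -0.13 in replicate 3. Over 5918 genes, retained-intron shares were higher by a median of 1.60 and 2.94 points than in replicates 2 and 3. For 27 NF-kB primary genes the median share, not paired by gene, was not higher in replicate 1 (45.5%, 51.9% and 46.0% in replicates 1, 2 and 3). Their mean share was 48.6%, 49.0% and 47.0%, above replicate 3 only. For 10 immediate early genes the median share was higher in replicate 1 (40.2%, 37.6% and 33.6%). However, mitochondrial mRNAs were higher in replicate 1 in 7 of 7 genes (0.48, above their matched range), and housekeeping genes lay at 0.02. The 37 rapid response genes with a share lay at 0.58. That was above 0.20, the upper end of the central 95% of lists matched on expression and on that share. A stronger response predicted a value above that bound. The 37 genes are part of the 78 that show the pattern, and matching used each gene's mean share over the libraries. The value therefore restates the pattern and is no separate test of a stronger response. That response and a replicate further along the response both stay open as hypotheses. For a replicate further along, the mean ratio of immediate early genes was below that of NF-kB primary genes. The log2 difference was -0.71 (permutation test over genes, p = 3e-05), which restates the gap already seen. NF-kB primary genes did not differ by a called amount from the later interferon response genes (0.07, permutation test over genes, p = 0.669). The RNA amount cannot be told apart from these hypotheses, as each amount was 1 library. Replicate 3 lay between the others for 65.4% of the genes.

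If replicate 1 were further along, longer genes, which are transcribed to their end later, might show larger ratios. Across the same 78 genes, which are not independent replicates, Spearman's rho between gene span and ratio was 0.21 (permutation p = 0.0613) and Pearson's r on log2 span 0.18 (permutation p = 0.106), or 0.21 without the 2 genes farthest from the median span. These 2 p-values, unadjusted, do not decide the question; over 13915 other genes rho was -0.05.

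Genes of the annotation class TEC, single-exon models awaiting experimental evidence, that lie inside introns on the strand of their host held 69.3% of all TEC counts. Gm37084, inside Mapkapk2 (chromosome 1, 131086252 to 131092149), alone had 49296, 35585 and 41352 counts in replicates 1, 2 and 3. Unspliced RNA of the host gene is a candidate source: rho between TEC and host levels was 0.70 over 788 genes on the host strand and 0.60 over 122 on the opposite strand, a difference of 0.10 (permutation test, p = 0.0888). The prediction had counted a difference no larger than chance against this source, which was wrong, because a p above the threshold excludes nothing and counting without strand would give both classes the host's reads. The 2 strands' difference therefore leaves it open, and no biological explanation was tested.

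Mitochondrial genes mt-Atp6, mt-Co2, mt-Nd3 and mt-Nd4l had 0 expected counts in 2 of the 3 libraries each. Reads shared with near-identical nuclear copies are a likely cause: each of the 4 has an annotated nuclear transcript of at least 95% identity over at least 80% of its length, and with its copies the smallest sum in a library at 0 was 59 counts. For mt-Atp6 the sums with Gm10925 were 454, 325 and 397 counts against 0, 157 and 0 for the gene alone, and mt-Co3, at 1.74, 1.05 and 0.73 counts, had 1192, 969 and 818 with Gm28437. No biological explanation was tested.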
